A study of Homo sapiens with 3 samples.

How the data were processed

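RNA from the human prostate cancer line DU145 was measured 48 h after transfection with 75 nM siRNA. There were 3 libraries: 1 with a control siRNA, 1 with TSPAN18 siRNA 1 and 1 with TSPAN18 siRNA 2. Samples were assigned to a control group and a siTSPAN18 group from their labels. Nothing in the labels says that the libraries came from separate cultures of one condition, and the 2 siTSPAN18 libraries came from different siRNAs.

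Per the submitters' processing notes, bcl2fastq 2.19.1, HISAT2 2.1.0, HTSeq 0.6.1 and the hg19 genome build were used. The annotation release, the strand setting and the siRNA sequences are not given in the sources used here. The deposited tables give 1 normalised value per gene, which the authors' values show to be CPM (counts scaled to a fixed library total): the listed genes of each library sum to 999868, 999861 and 999863. In each library 100% of the values were whole numbers of reads within a tolerance of 0.001 read, so read numbers could be recovered. Apart from genes at exactly 1 read (163, 178 and 97 genes in the control, siRNA 1 and siRNA 2 tables), every recovered number was even. Each pair therefore appears to have been counted as 2 reads, and a count of 0 appears to have been written as 1 read. No gene is listed at 0. The control and siRNA 1 tables list the same 23813 genes and the siRNA 2 table lists 23995. In all, 22773 genes are in the 3 tables, 1040 are missing from the siRNA 2 table (none above 0.769 CPM) and 1222 are in the siRNA 2 table alone (none above 0.504 CPM). Genes that were not tested held at most 0.300% of the reads of a library.

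The recovered depth was 30058731 read pairs for the control, 29913825 for siRNA 1 and 29766559 for siRNA 2, so that 1 pair is worth 0.0333, 0.0334 and 0.0336 CPM. The limit that a count of 0 allows (3 pairs) is 0.0998, 0.100 and 0.101 CPM. Poisson and exact (Clopper-Pearson) intervals at 95% cover counting error only. They carry no information on variation between cultures, and PCR copies are not independent molecules.

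Ratios were taken as log2(CPM + 1), a scale that understates the change of genes with low values. Genes with a mean of at least 1 CPM over the 3 libraries were kept (14185). Because the unit was CPM and not raw counts, the main test was the one planned for normalised values: limma 3.58.1 (eBayes, in R 4.3.3) with 2 siTSPAN18 libraries against 1 control and 1 residual degree of freedom. The spread comes from the siRNA pair alone and the lone control is assumed to vary like them. It is also shared across genes (6.27 prior degrees of freedom), so the spread of a single gene counts for little. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. As alternatives added after the unit was known, recovered read pairs were tested with edgeR 4.0.16, DESeq2 1.42.0 and limma-voom. Beside these tests stands a rule of size without any p-value: a gene counted when its ratio to the control was at least 2-fold in the same direction with both siRNAs. The comparison of siRNA 2 with siRNA 1 used the same 2-fold rule. Other work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

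Before the data were examined, 35 gene lists were fixed. The median log2 ratio of each list was placed among 10000 random lists of the same size matched on mean expression in 10 bins. A list was said to stand apart when its percentile was above 97.5 or below 2.5 in the same direction with both siRNAs. Lists with fewer than 5 tested members were not ranked. Genes are not replicates, so a percentile describes these libraries. Named genes were also chosen by a rule fixed beforehand: TSPAN18, STIM1, TRIM32 and the ORAI genes, then the 12 genes highest and the 12 lowest with both siRNAs by the smaller of the 2 absolute log2 ratios (mean of at least 2 CPM, without pseudogenes and clone-named loci), up to 4 members of each list that stood apart and of the calcium, tetraspanin, epithelial-mesenchymal, bone and interferon lists, and the 5 highest and 5 lowest genes for siRNA 2 against siRNA 1. Genes named outside this rule are marked as such, and 1 gene that the rule takes is not reported here.

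Both siRNAs share 1 control, which correlates their ratios with no effect at all. Unchanged libraries were therefore simulated in 100 sets, once with counting error only and once with libraries that differ as much as the siRNA 2 and siRNA 1 libraries do. The control could not be split.

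GENCODE release 29 on GRCh38 was used for sequence properties alone (transcript GC content, overlap of exons, 3′ UTR sequence), matched by gene identifier. As it is not the authors' build, no coordinates are given. GC content was available for 99.8% of the tested genes. The GC trend of each ratio was removed with a lowess curve (fraction 0.3). Every sequence of 7 bases found in the 3′ UTRs of at least 100 tested genes was scored for how far the genes that hold it lie below other genes in 1 library relative to the others. The score was taken after adjustment for 3′ UTR length, GC content of the 3′ UTR and of the transcript, and mean expression. A gene with no annotated 3′ UTR was not searched (85.3% of tested genes had one). The 2 heptamers with the lowest score in each library define what is called a site below. Sites were also counted with heptamers found in a random set of the genes and looked for in the other genes, and the reverse, which gave the same heptamers in each library. The search for heptamers and the GC correction were chosen after seeing the data.

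Scripts were tested on simulated data with 200 changed genes among 14185. With a dispersion of 0.05 and the present design, limma recovered 1.49% of 2-fold, 58.2% of 4-fold and 89.4% of 12-fold changes, edgeR 11.9%, 85.1% and 100%, and the 2-fold rule 26.9%, 88.1% and 100%. In the same simulation the 2-fold rule took 0.386% of the unchanged genes. Alternatives to scaling, filter, pseudocount, fold threshold, test and list settings were run, and each siTSPAN18 library was left out in turn.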

Results

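RNA sequencing of DU145 cells, an androgen-independent human prostate cancer line, was used to compare a control siRNA with a pair of siRNAs against TSPAN18, a tetraspanin membrane protein. The study's title places TSPAN18 with STIM1, the calcium sensor of the endoplasmic reticulum, and TRIM32, an E3 ubiquitin ligase, in bone metastasis. There was 1 library for the control and 1 for each TSPAN18 siRNA, with 30058731, 29913825 and 29766559 read pairs. No condition had a replicate of its own, so the values below carry counting error only unless stated. Any p-value sets the mean difference from the control against the spread between the siRNA 1 and siRNA 2 libraries, pooled in part over genes. This spread between the siRNA libraries may be technical or may come from the reagents. These libraries differed by far more than counting error (chi-square per degree of freedom 66.8 over 14185 genes) and were kept as 2 libraries. Mitochondrially encoded genes took 7.27% of reads in the control, 7.16% with siRNA 1 and 7.84% with siRNA 2.

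The first question was whether each siRNA lowered its target. TSPAN18 (ENSG00000157570) stood at 16.9 CPM in the control library, at 1.37 CPM with siRNA 1 and at 1.51 CPM with siRNA 2, from 509, 41 and 45 read pairs. This is 8.09% of the control value with siRNA 1 (95% exact interval 5.74 to 11.1) and 8.93% with siRNA 2 (6.43 to 12.1). The log2 ratios were −2.92 and −2.84, a mean of −2.88 ± 0.0590 (SD, n = 2). TSPAN18 had the smallest adjusted p of all genes in limma, 0.302, and so did not pass the threshold in this design. Its adjusted p ranged from 4.94e-10 to 0.986 over the alternative tests and settings.

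Transcripts of the other proteins in the title differed much less. STIM1 stood at 100.2 CPM in the control and at 96.6 and 88.2 CPM with siRNA 1 and siRNA 2. TRIM32 stood at 42.9 CPM in the control and at 55.1 and 50.9 CPM, which are 128% (119 to 138) and 119% (110 to 128) of the control. ORAI1, the pore subunit of the store-operated calcium channel, was at 89.9, 75.6 and 85.2 CPM. ORAI2 was at 41.8, 36.9 and 25.03 CPM, so that the siRNA 2 library held 59.9% (54.7 to 65.7) of the control value. The 3′ UTR of ORAI2 holds a heptamer site for each library, siRNA 2 included, and whether the site lowers it was not tested. That of STIM1 holds a siRNA 2 site and that of TRIM32 a siRNA 1 site, also without a test. ORAI3, at 3.56, 2.24 and 2.15 CPM, shares 46.0% of its exonic length with another annotated gene and is uncertain. None of these genes passed limma (adjusted p of 0.992 or more). The signs of the small ratios depend on the correction: with the GC trend removed, the log2 ratios of STIM1 were 0.10 and −0.07 and those of ORAI1 were 0.10 and 0.15, against −0.05, −0.18, −0.25 and −0.08 without it. With median-of-ratios scaling the STIM1 ratio with siRNA 1 was 0.06.

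**Figure D1:**
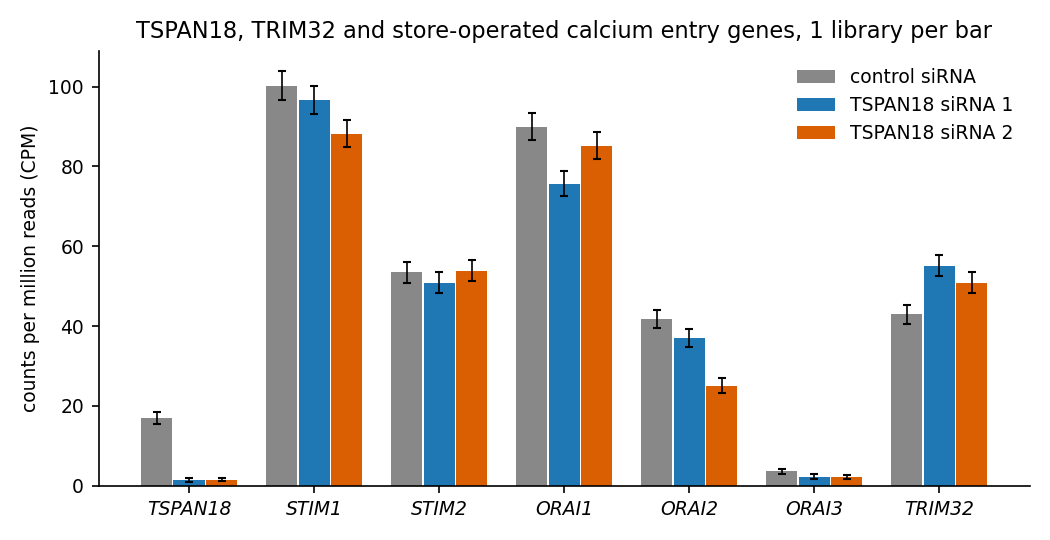
Expression (y axis, CPM) of TSPAN18, the STIM and ORAI genes of store-operated calcium entry and TRIM32 in the control library and in each TSPAN18 siRNA library, 1 library per bar, with error bars for 95% Poisson intervals of counting error. TSPAN18 is at 16.9 CPM in the control and at 1.37 and 1.51 CPM with the siRNAs, while STIM1 stays between 88.2 and 100.2 CPM.

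Across all genes, 37 were at least 2-fold higher and 60 at least 2-fold lower than the control with both siRNAs. The higher genes were led by ZNF664, a zinc finger gene, at 73.6 CPM in the control and 224.7 and 235.1 CPM with siRNA 1 and siRNA 2, and by G3BP2, a stress granule protein, at 72.0, 208.3 and 229.4 CPM. GANAB, the catalytic subunit of an endoplasmic reticulum glucosidase that trims N-glycans, was the most abundant of them at 281.5, 813.2 and 798.5 CPM. The other genes among the 12 highest were ZNF267, ZNF714 and ZNF41 (further zinc finger genes), ZW10 (a kinetochore protein, 22.1, 61.0 and 71.9 CPM), FOPNL, SETD7 (a lysine methyltransferase, 47.5, 123.0 and 146.8 CPM), HABP4, TPM4 (a tropomyosin, 118.0, 289.4 and 325.4 CPM) and OGFR. Their log2 ratios lay between 1.28 and 1.78 with siRNA 1 and between 1.29 and 1.66 with siRNA 2.

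The lower genes were led by TSPAN18 itself. TXNDC5, a protein disulfide isomerase, was at 7.78, 1.04 and 1.65 CPM, but 82.3% of its exonic length is shared with the readthrough gene BLOC1S5-TXNDC5, so its value is uncertain. CHCHD10, a protein of the mitochondrial intermembrane space, was at 55.3, 7.29 and 16.0 CPM. EGR1, an immediate early transcription factor, was at 23.8, 6.32 and 7.96 CPM. TERT, the catalytic subunit of telomerase, was at 22.3, 7.22 and 7.93 CPM. HS6ST1, a heparan sulfate sulfotransferase, was at 28.8, 10.0 and 7.96 CPM. TMEM158, ADGRA2, GPR37, KBTBD11, MFSD2A and SLC10A3 completed the 12 lowest, with log2 ratios between −1.85 and −1.31. ADGRA2 shares 23.5% of its exonic length with a gene on the opposite strand.

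No gene passed limma at an adjusted p of 0.05 over 14185 genes, while 691 had an unadjusted p under 0.05. On recovered read pairs, edgeR's quasi-likelihood test and limma-voom also called 0 genes, edgeR's likelihood ratio test called 23 (13 higher, 10 lower) and DESeq2 called 13 (10 higher, 3 lower). Genes called by both of the last tests included TSPAN18, ZNF664, G3BP2, GANAB, ZW10, CHCHD10 and TMEM158.

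**Figure D2:**
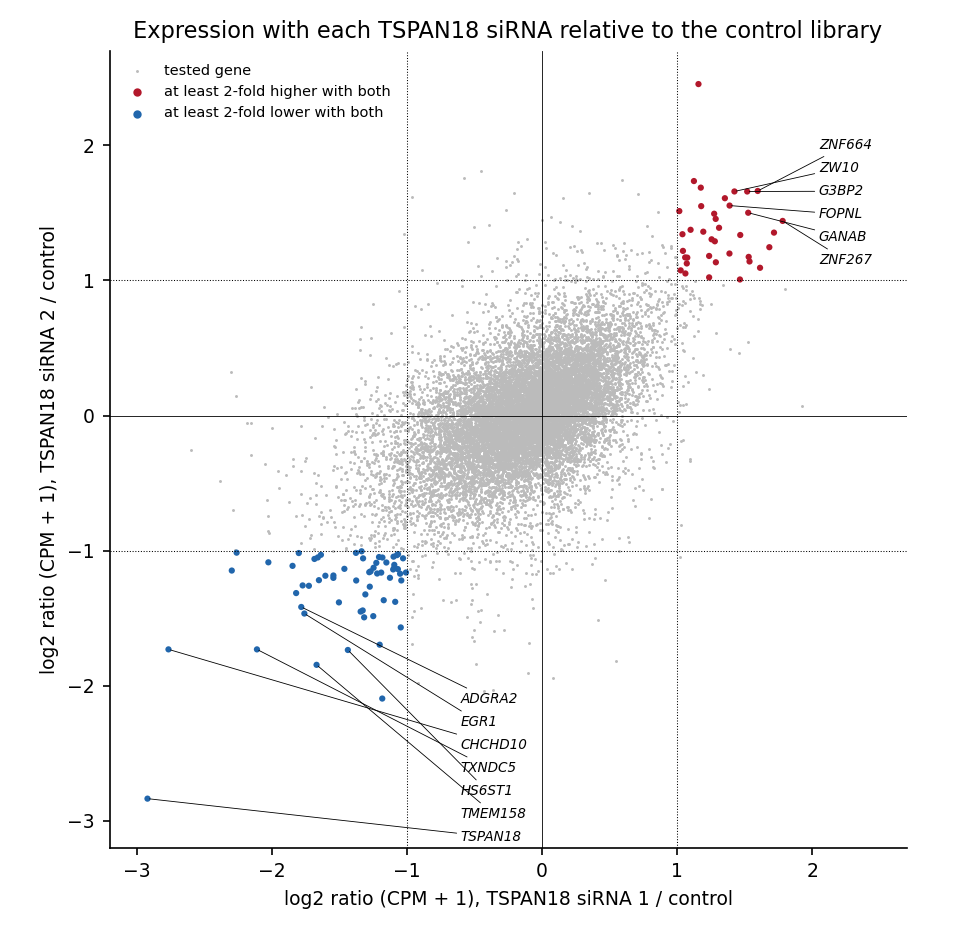
Log2 ratio (CPM + 1) to the control of each of 14185 genes with TSPAN18 siRNA 1 (x axis) and siRNA 2 (y axis), with the 37 genes at least 2-fold higher and the 60 at least 2-fold lower with both in colour. Dotted lines mark 2-fold. TSPAN18 lies apart at −2.92 and −2.84.

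The siRNAs differed in how many genes passed the 2-fold rule. With siRNA 1, 96 genes were higher and 597 lower, and with siRNA 2, 156 were higher and 164 lower. The median log2 ratio of all genes was −0.10 with siRNA 1 and 0.01 with siRNA 2. Median-of-ratios scaling set both medians within 0.01 of zero and gave 153 higher and 432 lower genes with siRNA 1, a share higher of 26.2% against 13.9%. The ratios of the siRNAs to the control correlated across genes (Pearson r = 0.518, Spearman rho = 0.50), and genes are not independent replicates. Unchanged libraries against a shared control gave r = 0.499 with counting error alone and 0.50 with libraries that differ as much as the siRNA libraries do. The covariance was 0.0966, against a simulated 0.0052 with counting error alone and 0.0921 with the larger spread. The latter simulation gave 81.6 genes at least 2-fold from the control with both siRNAs on average (range 61 to 102), beside the observed 97. Independent lists would share 1.06 higher and 6.90 lower genes. Part of the overlap may come from the shared control, which could not be split. The larger simulated spread includes any difference between the siRNA reagents, so it does not measure chance alone.

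The ratios also followed the GC content of the transcripts, as the plot by GC content shows. Spearman's rho of GC content with the log2 ratio, across genes, was −0.426 for siRNA 1 and −0.358 for siRNA 2, against 0.143 for siRNA 2 over siRNA 1. With this trend removed, 33 genes were higher and 34 lower with both siRNAs, of which 24 and 33 were among the 37 and 60. The simulation with the larger spread gave 79.1 genes on average with the trend removed, beside the observed 67. All of the 24 genes singled out above, chosen as the farthest past 2-fold, kept a ratio of at least 2-fold with both siRNAs after the removal. As a further measured property, 14 of the 36 higher genes with an annotated 3′ UTR (38.9%, exact interval 23.1 to 56.5) held a heptamer there that goes with low values in the control library, itself found from these libraries, against 4.18% of all genes with a 3′ UTR. Among the 12 highest genes it was present in 5, namely G3BP2, ZW10, SETD7, HABP4 and TPM4, and in none of the 12 lowest. Sites for siRNA 1 and siRNA 2 were in 3 and 1 of the 12 highest and in 2 and 5 of the 12 lowest. TSPAN18, HS6ST1, TERT, GPR37 and SLC10A3 held the siRNA 2 site. Of the 59 lower genes with a 3′ UTR, 23.7% (13.6 to 36.6) held a siRNA 2 site, against 14.7% of all. For siRNA 1 sites the shares were 16.9% and 23.9%. Whether the sites lower these genes was not tested.

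**Figure D3:**
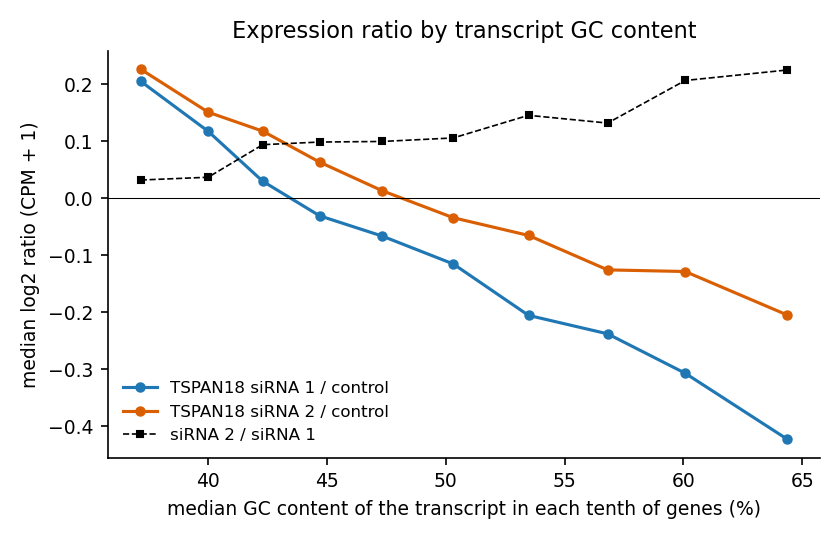
Median log2 ratio (CPM + 1, y axis) of genes in 10 groups of equal size ordered by transcript GC content (x axis, median GC of the group in percent), for each siRNA over the control and for siRNA 2 over siRNA 1. From the lowest to the highest GC group the median goes from 0.21 to −0.42 with siRNA 1 and from 0.23 to −0.20 with siRNA 2.

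Of 35 gene lists fixed beforehand, 32 could be ranked and 6 stood apart from random lists with both siRNAs, 2 higher and 4 lower. Both ratios share the 1 control and the simulation was not run on lists. How often lists or their members would go the same way with both siRNAs without an effect is therefore not known. No member of any list passed limma over all genes. Adjusted over the list alone, 1 member passed in the immediate early list (EGR1, adjusted p = 0.0300 in limma, lower with both siRNAs) and 1 in the neuroendocrine list (FOXA2, adjusted p = 0.0413, at 3.49, 1.24 and 1.01 CPM, named because it passed), and 0 in each of the other 30 lists.

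Genes of the amino acid and ATF4 response were higher as a group. The median log2 ratio of the 27 measured members was 0.46 with siRNA 1 and 0.61 with siRNA 2, at percentile 100 of the random lists with both. In all, 21 members were higher with both siRNAs, 8 of them at least 1.5-fold, and 1 was lower with both. TRIB3, a pseudokinase induced by ATF4, was at 90.1, 186.3 and 229.8 CPM. SESN2, a leucine sensor, was at 45.2, 91.2 and 99.4 CPM. PSAT1, an enzyme of serine synthesis, was at 366.8, 664.6 and 650.5 CPM, and the transcription factor ATF3 at 16.6, 31.0 and 49.1 CPM. The amino acid transporter SLC7A5, named after its values were seen, went apart, at 608.5 CPM in the control, 764.6 CPM with siRNA 1 and 310.7 CPM with siRNA 2. With random lists matched on GC content as well, the percentile stayed at 100. The unfolded protein response list did not stand apart with siRNA 1 (median 0.01, percentile 55.8), while it was at 0.18 and percentile 98.1 with siRNA 2.

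Replication-dependent histone genes were also higher, with medians of 0.37 and 0.45 over 11 members, of which 10 were higher with both siRNAs and 0 lower. HIST1H4H was at 4.86, 11.3 and 10.1 CPM and HIST1H2BD at 4.79, 8.83 and 11.02 CPM. HIST1H2BC and HIST1H2AG had log2 ratios between 0.45 and 0.87. These genes form a family of near-identical copies, most of whose messages lack a poly(A) tail, and their values are uncertain.

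DNA replication genes were lower, with medians of −0.21 and −0.28 over 30 members, 20 of them lower with both siRNAs and 2 higher. CCNE1, the cyclin of S phase entry, was at 43.6, 25.2 and 23.5 CPM. PCNA, the replication clamp, was at 126.4 CPM in the control, 46.8 CPM with siRNA 1 and 95.7 CPM with siRNA 2. MCM2 was at 217.5, 154.3 and 167.0 CPM, with 32.0% of its exonic length shared with other genes, and SLBP, which binds histone messages, at 178.1, 131.7 and 136.8 CPM. Without genes that hold a heptamer site the list no longer stood apart with siRNA 1 (percentile 4.06). The mitosis list did not stand apart (0.11 and −0.05).

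NF-kB and inflammatory cytokine genes were lower, with medians of −0.28 and −0.29 over 22 members, 15 of them lower with both siRNAs and 1 higher. The cytokine CSF2 was at 15.9, 6.45 and 2.96 CPM, TRAF1 at 36.4, 18.0 and 16.1 CPM, the chemokine CCL20 at 5.09, 2.47 and 2.39 CPM, and the adhesion molecule ICAM1 at 274.0, 182.2 and 184.1 CPM. ICAM1 shares 26.9% of its exonic length with other genes. The interferon response list did not stand apart (−0.02 and −0.01), with IRF1 at 24.2, 15.7 and 14.6 CPM and OAS3 at 159.5, 85.0 and 109.6 CPM on the lower side and IFI44 at 14.5, 22.1 and 19.01 CPM on the higher.

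Integrin and focal adhesion genes were lower, with medians of −0.19 and −0.28 over 26 members, 14 of them lower with both siRNAs and 4 higher. ITGB4 was at 61.6, 28.9 and 29.7 CPM, ITGA2 at 125.8, 68.7 and 81.5 CPM and ITGA3 at 1355, 998.8 and 979.1 CPM. Cytosolic ribosomal protein genes had medians of −0.25 and −0.13 over 39 members, 2 of them higher and 32 lower with both siRNAs, among the latter RPL14 (245.2, 181.1 and 148.1 CPM), RPS28, RPS23 and RPS2. Ribosomal protein genes have many processed pseudogenes that can share their reads. With random lists matched on GC content as well, neither of these lists stood apart: integrins were at percentile 4.03 with siRNA 1 and ribosomal proteins at 3.25 with siRNA 2. Without genes that hold a heptamer site their percentiles with siRNA 2 were 6.65 and 3.04.

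**Figure D4:**
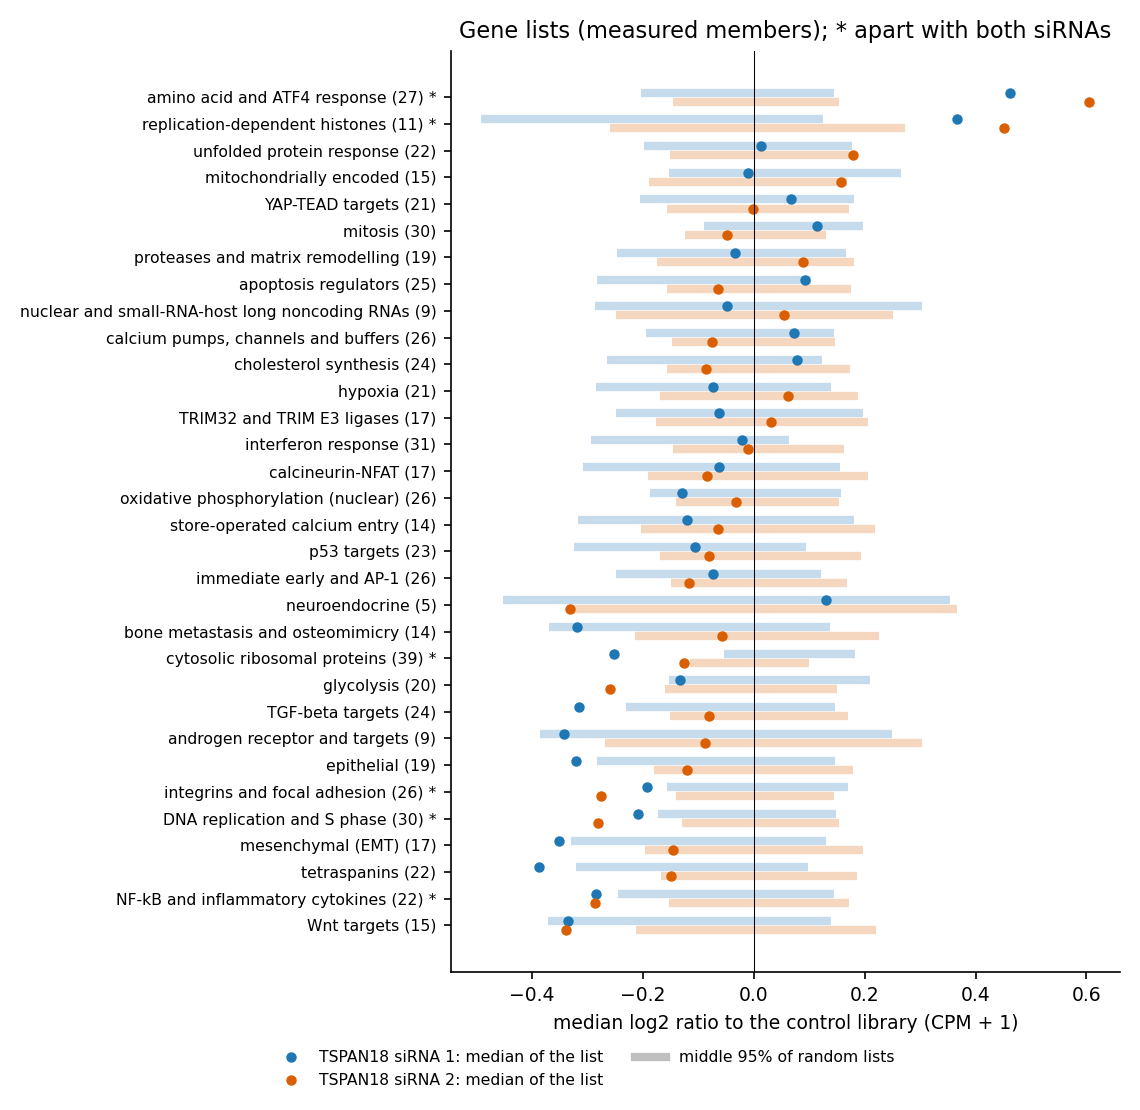
Median log2 ratio (CPM + 1, x axis) to the control of the tested members of each ranked list (y axis, number of members in brackets) with siRNA 1 and siRNA 2, over bars for the middle 95% of random lists matched on expression. An asterisk marks the 6 lists outside the bars in the same direction with both siRNAs, with the amino acid and ATF4 response highest at 0.46 and 0.61.

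The lists closest to the study's subject did not stand apart with both siRNAs by their medians. Store-operated calcium entry genes had medians of −0.12 and −0.06 over 14 members, with CRACR2B at 5.46, 1.70 and 2.89 CPM and JPH1 at 9.75, 5.28 and 5.64 CPM. Calcium pumps, channels and buffers had medians of 0.07 and −0.08, with 10 members higher and 10 lower with both siRNAs. ATP2A3, a calcium pump of the endoplasmic reticulum, was at 12.04, 4.38 and 4.84 CPM and S100A6 at 435.8, 288.8 and 303.4 CPM. SMDT1 was on the higher side, at 5.19, 6.92 and 8.47 CPM. The calcineurin-NFAT list was at −0.06 and −0.08. Tetraspanins were at −0.39 (percentile 0.570) with siRNA 1 and −0.15 (percentile 3.99) with siRNA 2, with CD82 at 19.5, 9.86 and 4.20 CPM and TSPAN33 at 25.6, 14.5 and 17.8 CPM. By the mean log2 ratio in place of the median they stood apart as lower (percentiles 0.10 and 0.36). Mesenchymal genes were at −0.35 and −0.15 and epithelial genes at −0.32 and −0.12, below percentile 2.5 with siRNA 1 and above it with siRNA 2, with ZEB1 at 48.3, 65.5 and 64.6 CPM, TWIST2 at 25.9, 16.7 and 11.02 CPM and ESRP2 at 32.8, 14.7 and 16.2 CPM. Without genes that hold a heptamer site, a setting chosen after seeing the data, epithelial genes stood apart as lower (percentiles 0.970 and 0.240). Bone metastasis and osteomimicry genes were at −0.32 and −0.06, with the cytokine IL11 at 107.8, 70.1 and 65.5 CPM, JAG1 at 9.28, 6.08 and 6.01 CPM and DKK1 at 80.3, 62.3 and 53.8 CPM. Of markers of other cell types, too few were measured for ranking: 4 fibroblast, 3 endothelial and 0 haematopoietic genes passed the filter, the highest being FBLN1 at 37.7, 25.6 and 25.9 CPM and EGFL7 at 33.9, 16.4 and 39.8 CPM.

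The siRNAs were also compared with each other. Between these libraries 404 genes were at least 2-fold higher with siRNA 2 than with siRNA 1 and 116 at least 2-fold lower. Median-of-ratios scaling gave 279 and 174. CD276, an immune checkpoint protein, was at 37.0 CPM with siRNA 1 and 233.5 CPM with siRNA 2, against 186.2 CPM in the control. The lysosomal genes TMEM9B and ARSB were at 5.08 and 4.38 CPM with siRNA 1 and at 31.2 and 26.3 CPM with siRNA 2. The antisense transcripts AL365181.3 and AL590666.2 were higher with siRNA 2 as well, with log2 ratios of 2.58 and 2.37. In the other direction, SLC4A8 was at 24.2 CPM with siRNA 1 and 3.90 CPM with siRNA 2, the growth factor TGFA at 192.9 and 45.2 CPM, the metalloprotease ADAM19 at 48.1 and 11.1 CPM and PEG10 at 290.9 and 75.5 CPM. RN7SL2, at 26.4 and 6.58 CPM, belongs to a family of near-identical copies and is uncertain. With 1 library per siRNA no test was made.

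Genes that differed between the siRNAs also differed in their 3′ UTRs. Of 353 genes with a 3′ UTR that were at least 2-fold higher with siRNA 2 than with siRNA 1, 49.6% (exact interval 44.2 to 54.9) held the heptamer TCACCAA or TTCACCA, against 23.9% of all genes with a 3′ UTR. CD276, TMEM9B and ARSB were among them. Of 107 genes at least 2-fold lower with siRNA 2, 55.1% (45.2 to 64.8) held TGGGTCA or GGGTCAA, against 14.7% of all. TGFA, SLC4A8, ADAM19 and PEG10 were among these. SLC4A8, ADAM19 and PEG10 also held a siRNA 1 heptamer but were not lower with siRNA 1, at log2 ratios to the control of 0.55, 0.08 and 0.42. Both pairs of heptamers were found from these libraries. The 436 genes that hold the full octamer TTCACCAA had a median log2 ratio of −0.27 with siRNA 1 and 0.07 with siRNA 2, against −0.09 and −0.01 in the 9208 genes without either heptamer. The 293 genes that hold the octamer TGGGTCAA were at −0.06 with siRNA 1 and −0.12 with siRNA 2, against −0.11 and 0.02 in the 10323 genes without either heptamer. The other genes with TGGGTCA or GGGTCAA were at −0.09 and −0.10.

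**Figure D5:**
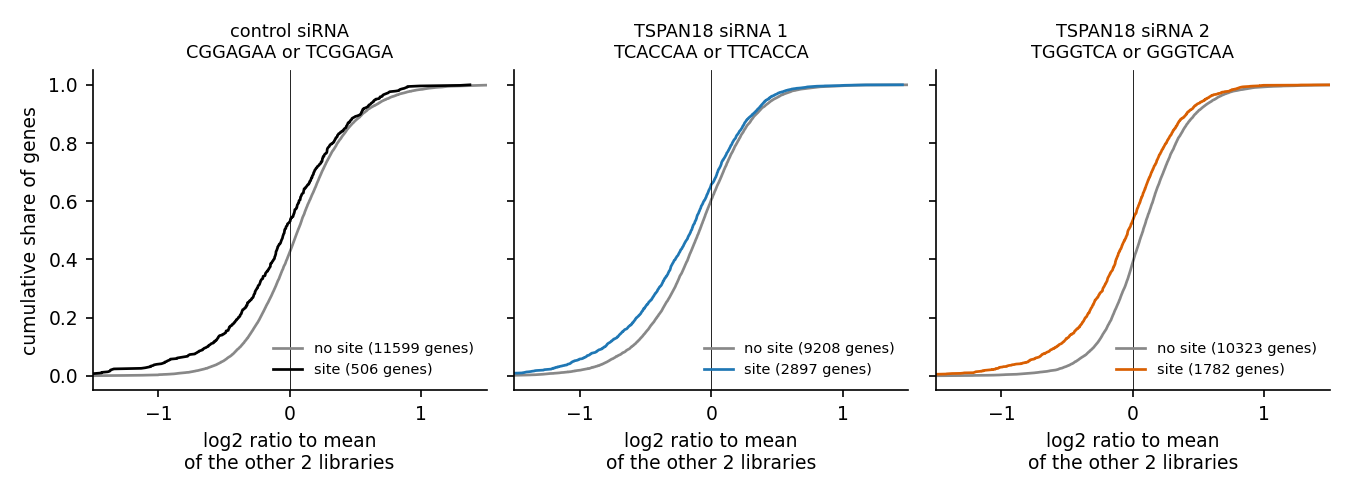
Cumulative share of genes (y axis) by log2 ratio (CPM + 1) of a library to the mean of the other 2 libraries (x axis), for the control, siRNA 1 and siRNA 2 libraries, split by whether the 3′ UTR holds one of the heptamers found from that library. In each panel the genes with a site lie to the left of those without, with 506, 2897 and 1782 genes with a site.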

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

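The genes in this part were picked by their values, and no test was made of them. TGFA was at least 2-fold higher than the control with siRNA 1 and at least 2-fold lower with siRNA 2, a log2 ratio of −2.07 for siRNA 2 over siRNA 1. AL590666.2 went the opposite way in each, with a log2 ratio of 2.37 for siRNA 2 over siRNA 1. Each siRNA has 1 library, so these differences were not tested. TGFA holds a 3′ UTR site for the heptamers that go with low values in the siRNA 2 library. AL590666.2 is annotated antisense to another gene, with 46.7% of its exonic length overlapping it, and whether reads were counted by strand is not given in the sources used here.

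In the genes left out of the comparisons because 1 table does not list them, 304 of the 1222 genes listed in the siRNA 2 table alone had more than the 3 read pairs that a count of 0 allows. The highest had 15 pairs, or 0.504 CPM. Their values in the other libraries were not analysed here.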

How the results depend on the processing

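The count tests on read pairs, the GC correction, the GC matching and the exclusion of genes with a heptamer site were chosen after seeing the data. No gene passed limma in the main analysis, with a mean of at least 5, without a filter, with pseudocount 0.1, with a trend or with the GC trend removed. Median-of-ratios scaling called 1 gene (TSPAN18). On read pairs, edgeR's quasi-likelihood test called 2 genes with DESeq2 size factors and 0 with TMM or total counts, edgeR's likelihood ratio test 23, DESeq2 13 and limma-voom 0. Leaving out either siTSPAN18 library leaves 1 against 1 and no test; by the 2-fold rule 320 to 693 genes then pass, as a single library has to pass and not both.

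The 37 higher and 60 lower genes with both siRNAs became 278 and 491 at 1.5-fold, 1 and 4 at 3-fold, and 70 and 136 with pseudocount 0.1. A mean of at least 5 gave 37 lower genes, removal of the GC trend 34 lower, and exclusion of genes with a heptamer site 19 higher and 37 lower. With 1 siRNA left out, the counts ranged from 96 to 156 higher and from 164 to 597 lower. Genes higher with siRNA 2 than siRNA 1 (404) became 38 at 3-fold, 807 with pseudocount 0.1 and 207 without genes with a site; lower genes (116) became 11 at 3-fold and 50 without genes with a site. Fewer genes enter when genes with a site are left out; the cause of the other shifts was not tested beyond the threshold itself. The correlation of the siRNAs (0.518) was 0.444 with the GC trend removed and 0.540 without genes with a site.

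The mean log2 ratio of TSPAN18 was −3.47 with pseudocount 0.1 and −2.77 with the GC trend removed, and −2.92 to −2.84 with 1 siRNA left out. The 6 lists that stood apart numbered 9 to 10 when 1 siRNA alone had to pass. They numbered 9 with the mean log2 ratio, 7 with a mean of at least 5, and 4 with matching on GC content or without genes with a site. With the mean log2 ratio the lists that joined were tetraspanins, Wnt targets (percentiles 0.46 and 0) and glycolysis (0.66 and 0.15), all lower, and glycolysis also joined with a mean of at least 5 (2.29 and 0.13). Among the 14 lists with named genes, 63 values under alternatives kept their standing, 5 in 3 lists lost it and 2 in 2 lists gained it (tetraspanins with the mean log2 ratio, epithelial genes without genes with a site). The 24 genes highest and lowest with both siRNAs all stayed at least 2-fold under median-of-ratios scaling, pseudocount 0.1 and the GC correction. They were chosen as the farthest past 2-fold, so this was likely in advance and says nothing of the other genes. Of 83 genes taken by the naming rule, without TSPAN18, the GC correction moved 43 by more than the SD of the siRNAs. No called direction was reversed. For genes this was likely in advance, since only genes at least 2-fold from the control with both siRNAs could count as reversed. The alternatives planned for raw counts (another prior count, DESeq2 size factors, total counts) were not run on ratios, since the unit was CPM; the ratios were recomputed with median-of-ratios scaling and pseudocount 0.1. No paired analysis was possible because there is 1 control library and the groups share a single replicate number. Depth limits genes near 0.1 CPM, but not TSPAN18, whose lowest count was 41 pairs.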

Other observations

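The zinc finger comparison, the split-gene tests of heptamers, the GC corrections and the exclusion of genes with a heptamer site were chosen after the result had been seen. Genes whose symbol starts with ZNF, most of them zinc finger transcription factors, were slightly higher as a group, a set looked at because several were among the highest genes. The 402 tested members had a median log2 ratio of 0.10 with siRNA 1 and 0.23 with siRNA 2, above all 2000 random lists matched on expression and also above all 2000 matched on expression and GC content. In this family 8 genes were at least 2-fold higher with both siRNAs and 0 at least 2-fold lower, and with the GC trend removed 5 were at least 2-fold higher with both. At 1.5-fold the counts were 37 and 2. Without the 8 genes at 2-fold the other 394 had medians of 0.10 and 0.23, again above all 2000 random lists of either kind, with 204 members higher and 80 lower with both siRNAs. Members share repeated domains, and reads split between them were not assessed. Both ratios share the 1 control library, and whether a difference in that library gives this shift was not tested.

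Each library had its own 3′ UTR heptamers that went with low values. For siRNA 1 the heptamer most depleted in a random set of 6052 genes, TTCACCA, had a z of −10.7 in the other 6053 genes. For siRNA 2 it was TGGGTCA with −10.0, and for the control CGGAGAA with −6.03, which ranked 2, 1 and 1 of 14309 heptamers there. The low z values of these heptamers remained after adjustment for GC content. The reverse complements, with equal GC content, had z values of 1.13, 0.139 and −0.129. As GC content was adjusted for before scoring, small values were likely in advance and do not decide on the base composition of 3′ UTRs. A candidate explanation is that each siRNA lowers transcripts with short matches to it, as siRNAs are known to do through their seed region. Both annotated TSPAN18 transcripts hold TTCACCAA, TGGGTCA and GGGTCAA, and neither holds the control heptamers or the octamer TGGGTCAA that the siRNA 2 heptamers form, although 9.72%, 20.98% and 13.3% of transcripts of similar length hold each by chance. The siRNA sequences are not given in the sources used here, so this stays a hypothesis.

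The 97 genes at least 2-fold from the control with both siRNAs may come from TSPAN18 or from the 1 control library they share. Libraries simulated to differ as the siRNA libraries do reached 97 genes in 8 of 100 sets. The sets held at most 55 higher and 57 lower genes, against the observed 37 and 60, or 44 and 50 with median-of-ratios scaling. With the GC trend removed, 89 of 100 sets reached the observed 67 genes. The spread put into these sets is that between different siRNAs, so it includes any effects of the reagents beside chance. The counts therefore cannot decide between a control library that differs by chance and an effect of TSPAN18. Both stay open, and an effect of TSPAN18 was not tested. Median log2 ratios were also compared before and after removal of the GC trend, for each gene with the siRNA of smaller change. They moved from 1.18 (quartiles 1.08 to 1.31) to 1.13 (0.97 to 1.31) in the higher genes. In the lower genes they moved from −1.14 (−1.26 to −1.05) to −1.03 (−1.15 to −0.86). The medians of the GC groups only spanned 0.21 to −0.42 with siRNA 1 and 0.23 to −0.20 with siRNA 2. Removal of a trend of that size could not undo ratios picked at 2-fold. These shifts therefore cannot decide whether a GC-dependent yield is the whole cause. They show only that the average trend over all genes is smaller than these ratios. As the cause of these genes passing 2-fold, a GC-dependent yield cannot be told apart from an effect. After the removal 24 of 37 and 33 of 60 still passed, between the bounds set beforehand. The other 13 and 27, with medians of 1.18 and −1.05 before, ended at 0.94 and −0.84, below the threshold but past 1.5-fold. Sites for control heptamers found in the other set of genes were in 38.9% of the higher genes with a 3′ UTR (14 of 36, exact interval 23.1 to 56.5), against 4.18% of all. This lies between the bounds set for it. When genes with a site for any library were left out, 19 higher genes remained. These values argue against such sites as the cause in all of the higher genes. In the 14 genes that hold one, a site cannot be told apart from an effect as the cause. Only the 2 lowest-scoring control heptamers in annotated 3′ UTRs count as sites. Others also scored low in the control library, such as AGGAGAA (z −6.54) and GGAGAAA (−6.24). Other matches to the control siRNA therefore stay open in the remaining higher genes.

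The amino acid and ATF4 response genes were higher with both siRNAs. GC-dependent yield is argued against as the cause, as the lower of the 2 percentiles was 100 with random lists matched on GC content. Only 2 of the 27 members hold a control heptamer site, which argues against these sites in the genes themselves as the cause for the group. The lower percentile was also 100 without genes that hold a site. With so few control sites this was likely in advance and decides nothing further. Other matches to the control siRNA were not counted as sites and stay open. A state of the 1 control culture unrelated to TSPAN18 cannot be told apart from an effect of the siRNAs, because at least 2 control cultures would be needed. A response to lowered TSPAN18 is therefore a hypothesis. A further control library would address only the state of the control culture. It would not separate lowered TSPAN18 from other effects of the control siRNA or of the TSPAN18 siRNAs.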
